A study of Mus musculus with 8 samples.

How the data were processed

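Single-cell RNA was measured with Seq-Well, a method that captures cells with barcoded beads in small wells, in 8 libraries from CT26 tumours of wild-type BALB/c mice. The labels call the cells myeloid and give 4 numbered libraries as high and 4 as low for latency-associated peptide (LAP). Each library came as 1 deposited table of whole-number counts per gene and cell barcode, not normalised. STAR 2.5.3a, Seurat 3.0 and genome build GRCm38 are named per the submitters' processing notes, with no role given. The gene annotation, the counting tool, the use of strand and the rule that chose barcodes are not given in the sources used here. Whether the authors collapsed reads with the same molecular identifier into 1 count is not stated either. If they did not, the deposited counts are reads and not independent molecules. Limits and intervals from counts therefore cover counting error only.

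Each table held 10000 barcodes of 12 bases and between 27731 and 36313 genes, and the union of genes over the 8 tables was 44400. Total counts ran from 5501256 to 15536651 per library. A barcode was kept as a cell when it had at least 500 counts, at least 300 genes and at most 15% of its counts from mitochondrial genes. Of 23892 barcodes that passed the limits on counts and genes, 12175 were also under the mitochondrial limit, with 45431722 counts. Kept counts ran from 3566528 to 7490451 per library. No doublets were removed in the results of the report. As an alternative, doublets were simulated from pairs of cells, with 2 simulated per cell and 40 neighbours, and the 5% of barcodes with the highest scores in each library, 608 in all, were removed.

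Counts of the kept barcodes were scaled to 10000 per cell and logged. Cells of all libraries were clustered together on 2000 variable genes, 30 principal components, 15 neighbours and the Leiden method at resolution 1.0, with no integration between libraries. This gave 22 clusters. A cluster was named from marker genes only, when at least 3 markers of 1 class led it and no other class had as many among its top 10 genes. A cluster with at least 4 cell cycle genes among its top 10 stayed unnamed, a rule set after the clusters were seen. In all, 17 clusters with 10655 cells were named, and names are written as "-like". The other 5 clusters kept their numbers and are described by their leading genes. A single cluster held markers of both fibroblasts and tumour epithelium and forms the fibroblast/tumour class, and clusters of monocytes and macrophages form 1 class.

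The test of genes used counts summed per library, because cells are not replicates. Sums were made over all kept cells, and within a class over the libraries with at least 20 cells of it, where at least 3 libraries per group had them. The 5 comparisons tested were all cells, monocyte/macrophage-like, NK cell-like, T cell-like and pDC-like (plasmacytoid dendritic cell-like) cells. Genes were tested with edgeR's quasi-likelihood test after its default filter on low counts and TMM scaling, with group as the only term and Benjamini-Hochberg adjustment over the genes tested. A gene was called at an adjusted p under 0.05. Levels are given as TMM-normalised CPM, mean ± SD over 4 libraries, and fold changes are LAP-high over LAP-low on the log2 scale.

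Lists of genes were fixed beforehand, 17 of cell type markers and 20 of functions, and tested with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. A list was tested when at least 3 of its genes passed the filter. The marker lists were neutrophil, monocyte, macrophage, conventional dendritic cell types 1 and 2 (cDC1, cDC2), mature DC, pDC, T cell, NK cell, B cell, mast cell or basophil, eosinophil, tumour epithelial, fibroblast, endothelial, erythroid and platelet. The eosinophil, erythroid and platelet lists had too few genes past the filter in every comparison and have no result. The functional lists were LAP and latent TGF-β handling, TGF-β response, immunosuppressive effectors, MHC class II presentation, MHC class I presentation, T cell costimulation, type I interferon response, interferon-γ response, inflammatory cytokines, chemokines, glycolysis, hypoxia, lysosome and lipid handling, phagocytic and scavenger receptors, matrix remodelling and angiogenesis, cell cycle, immediate early and heat shock, neutrophil granule proteins, ribosomal proteins and mitochondrially encoded genes. Some genes stand in more than 1 list, such as Vegfa, Trem2 and Cxcl10. Camera with an estimated correlation and limma's fry test, which asks whether the genes of a list move 1 way on balance, were alternatives.

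Shares of cells were compared with exact two-sided permutation tests over the 70 assignments of the 8 libraries, with Benjamini-Hochberg adjustment over the 12 classes and unnamed clusters tested. The smallest p these can give is 0.0286.

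Groups, tests, filters, lists, markers, the rule for named genes and the first set of alternatives were chosen before the data were examined. The rule named, over all kept cells, the 12 largest increases and 12 largest decreases among called genes with a mean of at least 50 CPM and no overlap between the groups. It also named up to 4 genes with the lowest adjusted p from each functional list, and Tgfb1, Lrrc32 and Nrros whatever their p. Within a class it named up to 6 genes per direction, or the 3 with the lowest p where none passed. Some genes that the rule names are not reported here. Genes named outside this rule are pointed out as chosen after their values were seen. Named genes were looked up in GENCODE vM21, an annotation of GRCm38. All 112 symbols matched 1 gene each; 53 overlap another annotated gene and 21 overlap a protein-coding gene. Counts of overlapping genes, and of close relatives such as the immunoglobulin, MHC, granzyme and ribosomal protein families, are uncertain to that extent.

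The tests were tried on simulated counts with 200 genes changed, drawn with the means and library sizes of each comparison. edgeR recovered 16% of 2-fold and 73.7% of 4-fold changes over all cells (12613 genes). It recovered 38.7% and 96.9% in monocyte/macrophage-like cells (8527 genes), 53.5% and 91.9% in NK cell-like cells (8929 genes), 24.5% and 83.7% in T cell-like cells (7910 genes), and 48.5% and 98.9% in pDC-like cells (2163 genes). No pair of libraries of a group was as alike as sampling noise allows, the lowest chi-square per degree of freedom being 16.0, so each library was counted once.

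Alternatives fixed beforehand were other size factors, the replicate number as a block, each of the 8 libraries left out in turn, looser limits (300 counts, 200 genes), stricter limits (1000 counts, 500 genes), no mitochondrial limit, removal of doublets, no filter on low counts, DESeq2, all barcodes, thinning to 3566528 counts per library, averages of per-cell CPM tested with limma, cluster resolutions 0.5 and 2.0, and log odds for shares. Alternatives chosen after seeing the data were a batch term and fits within each batch, subtraction of free RNA, the myeloid-like cells alone, and the replicate block together with an estimated correlation. The batches were read from the numbering of the libraries, which falls into 2 series: replicates 1 and 2 of both groups form batch A, and replicates 3 and 4 form batch B. The labels name no batch. Whether replicate numbers pair the libraries was judged per comparison, from the correlations of deviations of same-numbered libraries from their group means, since the labels do not say what a number marks. In T cell-like sums these were 0.130 to 0.416, over 0.1 in 4 of 4 pairs, and there the blocked result is given beside each result it changes. Judging this per comparison and not over whole libraries was chosen after the calls of the blocked fits had been seen. A number that marks a shared source would do so in every class of the same libraries. The rule therefore does not settle what a number marks, and blocked and unblocked counts of calls are both given. Free RNA was estimated from barcodes with 10 to 100 counts.

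Work used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, leidenalg 0.10.2, igraph 0.11.9 and Matplotlib 3.10.9. No genes but the LAP genes in cluster 13 were tested within conventional DC-like, neutrophil-like or fibroblast/tumour-like cells or unnamed clusters, as too few libraries held 20 such cells or the cluster had no name. No reads were analysed here.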

Results

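To ask how myeloid cells of a tumour that carry latency-associated peptide (LAP) on their surface differ from those with little of it, single-cell RNA was measured from CT26 tumours of BALB/c mice. CT26 is a transplantable mouse colon carcinoma line. LAP is the propeptide of the Tgfb1 product and holds TGF-β1 in an inactive, latent complex. There were 4 LAP-high and 4 LAP-low libraries, which the design text calls biological replicates. Whether each came from its own mouse or from pooled mice is not given in the sources used here, so p-values measure the spread between these libraries. The LAP-high libraries 1 to 4 held 15536651, 7217098, 8989281 and 5501256 counts. The LAP-low libraries held 10477933, 13751307, 8193797 and 9414908. After filtering, 12175 cells were kept, between 1090 and 2021 per library. Median counts per kept cell were 2453 ± 704 in LAP-high and 1743 ± 264 in LAP-low libraries (SD, n = 4).

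The mitochondrial limit removed different shares of barcodes from the libraries. Among barcodes past the limits on counts and genes, it kept 27.3% in LAP-high 1, 67.1% in LAP-high 2, 83.1% in LAP-high 3 and 86.8% in LAP-high 4. It kept 45.8%, 34.0%, 53.4% and 56.5% in LAP-low 1 to 4. Libraries 1 and 2 of both groups (batch A) and libraries 3 and 4 (batch B) belong to different numbering series, so values are also given within each batch of 2 libraries per group.

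The genes behind surface LAP were compared first, since the libraries are named for that protein and RNA need not follow it. RNA of all 3 genes was higher in the LAP-high libraries. Tgfb1, which encodes LAP together with TGF-β1, had 232 ± 116 CPM in LAP-high and 70.8 ± 32.6 CPM in LAP-low libraries (mean ± SD, n = 4 each). Its log2 fold change was 1.71 (SE 0.428, edgeR adjusted p = 0.0242), although the values of the groups overlapped. Nrros, whose product LRRC33 anchors latent TGF-β1 on myeloid cells, rose from 40.4 ± 13.9 to 169 ± 71.3 CPM (log2 fold change 2.06, SE 0.369, edgeR adjusted p = 0.00731). Lrrc32, whose product GARP anchors it on regulatory T cells and platelets, was rare, at 5.26 ± 2.95 against 0.946 ± 0.653 CPM (log2 fold change 2.46, SE 0.590, edgeR adjusted p = 0.0203). In GRCm38 coordinates Tgfb1 lies on chromosome 7 from 25687002 to 25705077 on the plus strand, Lrrc32 on chromosome 7 from 98489283 to 98502181 on the plus strand, and Nrros on chromosome 16 from 32142785 to 32165594 on the minus strand; none of them overlaps another annotated gene.

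**Figure D1:**
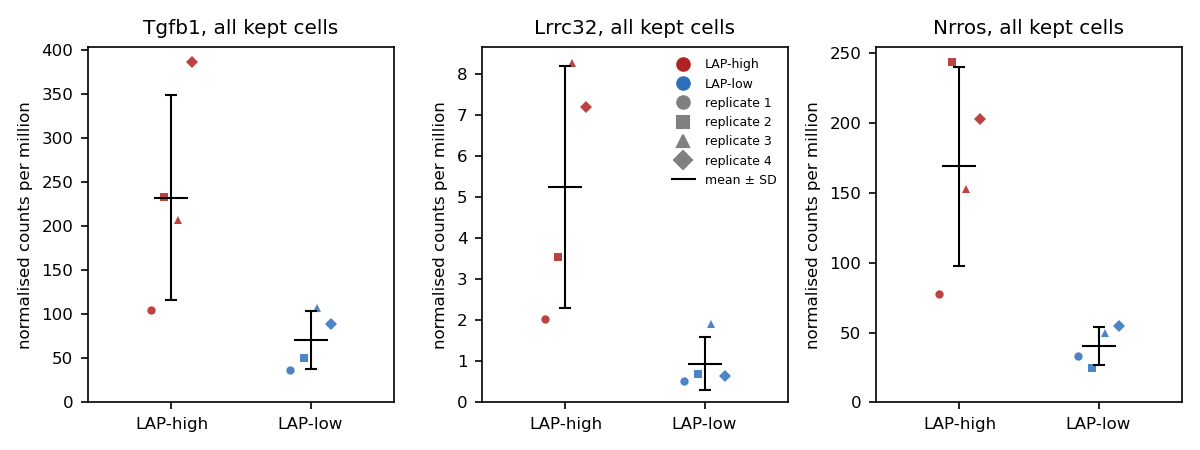
Normalised CPM of Tgfb1, Lrrc32 and Nrros over all kept cells, 1 point per library with marker shapes for the replicate number, and mean ± SD per group (n = 4). Lrrc32 and Nrros do not overlap between the groups, with means of 5.26 against 0.946 CPM and 169 against 40.4 CPM, while Tgfb1 does.

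These genes were read from different cells. In LAP-high libraries monocyte/macrophage-like cells held 72.6% of Tgfb1 counts and 74.0% of Nrros counts, and cluster 11, led by Ace, Adgre4 and Cd300e, had the highest Nrros level at 383 ± 52.3 CPM. Most Lrrc32 counts of LAP-high libraries lay in cluster 13, led by Foxp3, Ikzf2 and Ctla4, genes of regulatory T cells. That cluster held 76.6% of them, 82 counts in 4 libraries. In LAP-low libraries T cell-like cells held 54.5% of Lrrc32 counts and cluster 13 held 31.8%, which are 12 and 7 counts. There NK cell-like cells held 34.2% of Tgfb1 counts and monocyte/macrophage-like cells 24.5%, and of Nrros counts they held 22.8% and 35.1%. Within monocyte/macrophage-like cells Tgfb1 had a log2 fold change of 0.64 (edgeR adjusted p = 0.691) and Nrros of 0.41 (edgeR adjusted p = 0.719), so neither passed there. In NK cell-like cells the values were 0.54 (edgeR adjusted p = 0.774) and 0.26 (0.936), and in T cell-like cells 0.16 and −0.24 (both 1). Within batch A the log2 fold changes over all cells were 1.96 for Tgfb1, 2.15 for Lrrc32 and 2.497 for Nrros (edgeR adjusted p = 0.173, 0.366 and 0.170). Within batch B they were 1.59, 2.61 and 1.76 (0.0111, 0.00741 and 0.000237). The Tgfb1 call was lost without LAP-low 1 (1.4999, edgeR adjusted p = 0.0555), LAP-high 2 (1.74, 0.06), LAP-low 2 (1.58, 0.0675) or LAP-high 4 (1.34, 0.0778). The Lrrc32 call was lost without LAP-low 1 (2.27, 0.052), LAP-low 2 (2.34, 0.0588), LAP-high 3 (2.13, 0.0717), LAP-high 4 (2.28, 0.0644) or LAP-low 4 (2.33, 0.063). Over all alternatives the adjusted p ran from 4.02e-10 to 0.322 for Tgfb1, from 0.000771 to 0.366 for Lrrc32 and from 8.2e-16 to 0.398 for Nrros.

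Which cells made up each fraction was compared next. LAP-high libraries were mostly monocyte/macrophage-like cells, 61.8% ± 16.9 of kept cells against 11.4% ± 4.39 in LAP-low libraries (SD, n = 4 each), 5.44-fold more. LAP-low libraries were mostly lymphoid although the labels call all cells myeloid. NK cell-like cells made up 30.1% ± 3.52 of them and 10.5% ± 8.21 of LAP-high cells, and T cell-like cells 30.1% ± 4.89 and 5.88% ± 3.30. Fibroblast/tumour-like cells, with collagen and keratin genes, were 11.3% ± 5.52 of LAP-low and 0.396% ± 0.567 of LAP-high cells. Conventional DC-like cells, the dendritic cells that present antigen to T cells, were 2.51% ± 0.660 of LAP-high and 0.672% ± 0.334 of LAP-low cells. Cluster 11, whose leading genes Ace and Adgre4 are known from patrolling monocytes, made up 5.49% ± 1.20 and 0.971% ± 0.534. Cluster 16, with B cell and mast cell genes such as Cpa3, Igkc and Tpsab1, made up 0.379% ± 0.230 and 4.08% ± 4.40. As 7 of 7 mast cell or basophil markers were positive over all cells, this need not mean fewer mast cells.

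In each of these 7 cases the 4 libraries of the groups did not overlap, which gives the smallest p of the exact permutation test, 0.0286 (Benjamini-Hochberg adjusted p = 0.049 over 12 classes and clusters; chance gives non-overlap for 2.86%). The differences of shares in batches A and B were 50.01 and 50.8 percentage points for monocyte/macrophage-like, −17.8 and −21.4 for NK cell-like, and −25.7 and −22.6 for T cell-like cells. They were −14.5 and −7.43 for fibroblast/tumour-like cells, 1.5001 and 2.18 for conventional DC-like cells, 4.58 and 4.46 for cluster 11, and −1.26 and −6.13 for cluster 16, whose difference was −1.53 without LAP-low 3 and −3.70 with it. LAP-high 4 held 0 fibroblast/tumour-like cells of 1700, which allows a share of up to 0.176%. After removal of doublets none of the 7 passed (Benjamini-Hochberg adjusted p of the exact test = 0.0571 for 6 of them and 0.171 for cluster 16), because fewer of the 12 classes then reached the smallest p. With 1 library left out, 6 of the 7 passed only without LAP-high 2, where cluster 13 passed as well (exact test, Benjamini-Hochberg adjusted p = 0.049), and cluster 16 never passed. Without any other library the adjusted p of the exact test ran from 0.0571 to 0.098 for the 6.

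The remaining classes did not pass. Cluster 13, led by Foxp3, was 3.53% ± 1.34 of LAP-high and 1.99% ± 0.622 of LAP-low cells (exact permutation p = 0.0857, Benjamini-Hochberg adjusted p = 0.129, n = 4 each), with differences of 1.92 and 1.15 percentage points in batches A and B. Plasmacytoid dendritic cell-like (pDC-like) cells were 2.57% ± 0.652 and 2.62% ± 1.63 (exact permutation p = 1; 0.398 and −0.496 in batches A and B), neutrophil-like cells 1.62% ± 1.21 and 2.65% ± 1.75 (exact p = 0.429, adjusted p = 0.514; −0.129 and −1.92), and cluster 10, led by the cycling genes Mki67 and Top2a, 4.73% ± 5.23 and 3.84% ± 2.72 (exact p = 0.8, adjusted p = 0.873). Cluster 21, led by unnamed gene models, was 0.617% and 0.339% (exact p = 0.343, adjusted p = 0.457). All shares are of cells left by the separation on LAP, the limits on counts and genes, and the mitochondrial limit, with no doublets removed; median counts per cell differed between the groups as given above.

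**Figure D2:**
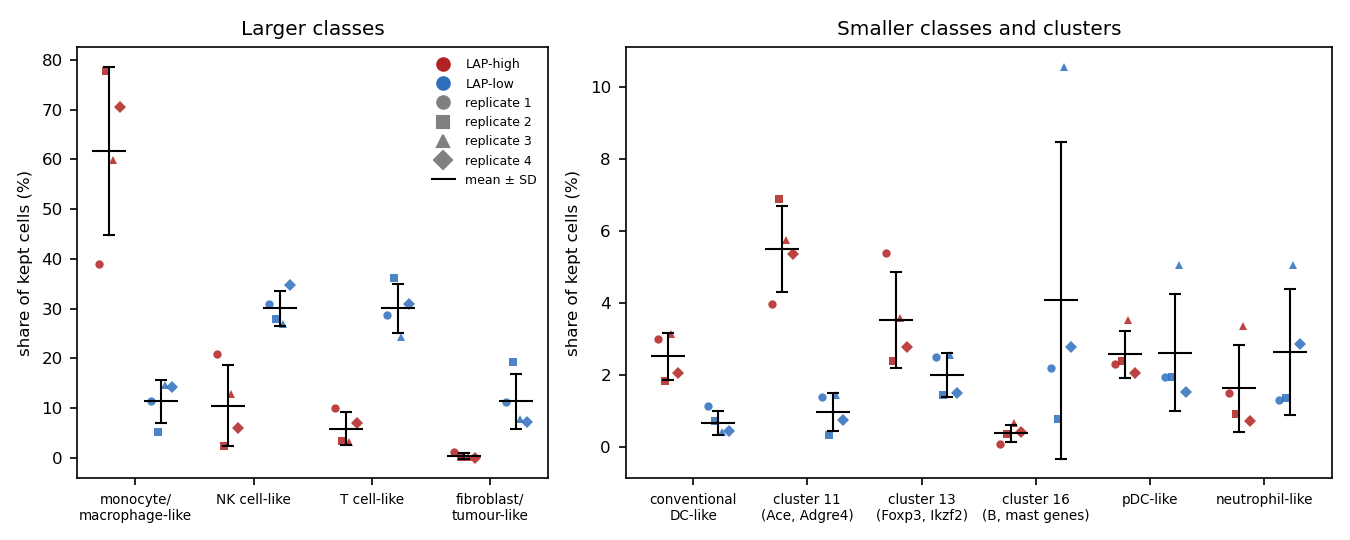
Share of kept cells in percent for 10 of the 12 classes and clusters, 1 point per library with marker shapes for the replicate number, and mean ± SD per group (n = 4). Monocyte/macrophage-like cells averaged 61.8% of LAP-high and 11.4% of LAP-low cells, and NK cell-like and T cell-like cells each averaged 30.1% of LAP-low cells.

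Gene expression was then compared over all kept cells. Genes of monocytes and macrophages were higher in the LAP-high libraries. The scavenger receptor Colec12 had a log2 fold change of 3.24 (SE 0.493, edgeR adjusted p = 0.00525; 291 ± 134 against 30.9 ± 14.3 CPM). The growth factor receptor Csf1r, needed by macrophages, rose by 2.94 (SE 0.458, edgeR adjusted p = 0.00536; 816 ± 327 against 106 ± 52.5 CPM), and the coagulation factor subunit F13a1 by 3.12 (SE 0.554, edgeR adjusted p = 0.00723; 698 ± 363 against 80.5 ± 44.2 CPM). Other large increases were Ace (3.12), the endosomal receptor Tlr13 (3.11), Ptpro (3.06), Plbd1 (3.04), Tifab (2.999), the metalloproteinase Mmp19 (2.97), haptoglobin, Hp (2.96), and Clec4a1 (2.96), with edgeR adjusted p between 0.00492 and 0.0102. The largest decrease was Tm4sf1, a membrane protein of epithelial tumours, with a log2 fold change of −5.86 (SE 0.640, edgeR adjusted p = 0.00178; 2.29 ± 1.75 against 153 ± 98.2 CPM). The caveola genes Cavin2 (−4.91) and Cavin1 (−4.42), Cald1 (−4.65), Baiap2l1 (−4.41), the collagen gene Col1a2 (−4.31) and Cd34 (−4.00) also fell, as did the antibody light chain Igkc (−4.00), the metallothionein Mt2 (−3.32), Anln (−2.91), the zinc transporter Slc30a4 (−2.71) and the T and NK cell chemokine Ccl5 (−2.42), with edgeR adjusted p between 0.00178 and 0.0147. Colec12 lies on chromosome 18 from 9707595 to 9882644 on the plus strand and overlaps 7 genes, none of them protein-coding. Tm4sf1 lies on chromosome 3 from 57285611 to 57301988 on the minus strand with no overlap. Csf1r on chromosome 18 (61100598 to 61132149, plus strand) overlaps Hmgxb3.

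Of 12779 genes tested, 2062 were called, 1405 higher and 657 lower in LAP-high libraries (68.1% higher). Groups did not overlap for 2428 genes, 19% of those tested, where chance gives 2.86%. Within batch A edgeR called 0 genes, with 1678 at an unadjusted p under 0.05, and within batch B it called 3169; DESeq2 over all 8 libraries called 2799. Called genes kept their sign in both batches (2060 of 2060, 2046 of 2046 tested), which selection on the same libraries favours. With each cell weighted equally, limma called 2531 genes, of which 1020 were higher (40.3%), and the median over all genes moved from −0.05 to −0.31. Without LAP-high 1, 2, 3 or 4 edgeR called 3954, 1116, 1223 and 1066 genes, and without LAP-low 2 or 4 it called 1347 and 1349. With the myeloid-like cells alone, a choice made after seeing the data, 102 genes were called, 8 higher and 94 lower, 34 of them shared with the 2062. There signs turned for Il1b, Osm, Slc16a3, Mmp14, Ncf1, Id1, Slc2a1, Ero1l, P4ha1 and Timp1. The class mix of these cells also differs (below), so turned signs and means need not be changes within a class.

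Marker lists of cell types differed as well. Of 12 macrophage markers 11 rose over all genes and 11 adjusted over the list alone (mean log2 fold change 2.13, camera adjusted p = 7.13e-12), among them the chemokine Pf4 (2.39) and the lipid receptor Trem2 (2.33). Of 10 monocyte markers 7 rose, and 8 adjusted over the list alone (mean 1.97, camera adjusted p = 2.33e-06), F13a1 among them. With an estimated correlation the adjusted p = 0.274 for both. Their means were 0.37 and 0.49 in the myeloid-like cells alone (camera adjusted p = 0.00489 and 0.00225; adjusted p = 0.254 for both with an estimated correlation). Of 9 cDC1 markers 4 rose, 5 adjusted over the list alone (mean 1.17, camera adjusted p = 0.000628; adjusted p = 0.274 with an estimated correlation; mean −0.022 in the myeloid-like cells alone). The 10 cDC2 markers had 2 higher and 1 lower over all genes, and 4 and 2 adjusted over the list alone (mean 0.97, camera adjusted p = 0.0228; adjusted p = 0.278 with an estimated correlation), and the call was lost without LAP-high 1 (mean 1.04, 0.0656). In the myeloid-like cells alone the cDC2 mean turned to −0.65 and was called lower (camera adjusted p = 0.00489; adjusted p = 0.13 with an estimated correlation). Mature DC (mean −0.37, camera adjusted p = 0.13), pDC (−0.42, 0.29), neutrophil (0.42, 0.25), mast cell or basophil (1.52, 0.144) and endothelial markers (1.70, 0.0531) did not pass. With the myeloid-like cells alone camera called mature DC (−1.01), pDC (−1.97) and neutrophil markers lower, the last with its mean turned to −1.66 (adjusted p = 0.00186, 4.73e-18 and 4.74e-16; adjusted p = 0.319, 0.126 and 0.126 with an estimated correlation). Over all genes and adjusted over the list alone alike, 1 of 8 mature DC markers was lower (Ccl5), 1 of 9 pDC markers was lower, 3 of 12 neutrophil markers and 2 of 4 endothelial markers were higher, and 0 of 7 mast cell markers were called by edgeR.

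Lymphoid and stromal markers were lower. Of 9 B cell markers 8 fell, 9 adjusted over the list alone (mean −3.57, camera adjusted p = 4.47e-06; adjusted p = 0.278 with an estimated correlation; mean −1.44 in the myeloid-like cells alone). Of 8 fibroblast markers 5 fell, 8 adjusted over the list alone, with Col1a2 among them (mean −3.51, camera adjusted p = 1.29e-07; adjusted p = 0.274 with an estimated correlation). Of 8 NK cell markers 2 fell, 6 adjusted over the list alone (mean −1.21, camera adjusted p = 0.000293), and of 11 T cell markers 0 fell over all genes by edgeR and 8 adjusted over the list alone (mean −0.9997, camera adjusted p = 0.000178). With an estimated correlation both had adjusted p = 0.315. The 5 tumour epithelial markers split, 1 higher and 2 lower over all genes, 2 and 2 adjusted over the list alone (mean −1.40, median −0.07, camera adjusted p = 0.114).

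Among the functional lists, genes that handle latent TGF-β moved apart. Of 12 measured, 7 rose and 3 fell, over all genes and adjusted over the list alone, and the list did not pass (mean 0.23, median 1.47, camera adjusted p = 0.116). The integrin subunit Itgb8, which can activate latent TGF-β (log2 fold change 2.87, edgeR adjusted p = 0.00552), and the protease Mmp14 (1.58, 0.00415) rose with the 3 LAP genes. Ltbp1 (−5.56, edgeR adjusted p = 0.00178) and Ltbp4 (−4.53, 0.00573), which tether latent TGF-β to matrix, fell with the fibroblast markers. Of 14 TGF-β response genes 4 rose and 1 fell, 5 and 1 adjusted over the list alone (mean 0.38, camera adjusted p = 0.0766; mean −0.040 in the myeloid-like cells alone). They included Tgfbi (2.68, edgeR adjusted p = 0.00536), Tgfbr1 (1.43, 0.00442) and Id1 (1.24, 0.0331).

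Genes linked to suppression and to antigen presentation were higher over all cells. Of 20 immunosuppressive effectors 11 rose and 1 fell, 15 and 1 adjusted over the list alone (mean 1.20, camera adjusted p = 7.34e-07; adjusted p = 0.274 with an estimated correlation), such as Wfdc17 (2.82), Trem2 (2.33), the prostaglandin synthase Ptgs2 (1.75) and the checkpoint ligand Vsir (1.54). Of 12 MHC class II genes 9 rose on both counts, 9 adjusted over the list alone (mean 1.40, camera adjusted p = 2.26e-07; adjusted p = 0.274 with an estimated correlation), such as Ctss (2.18), Ifi30 (2.10), H2-DMa (2.08) and H2-Eb1 (1.96). Of 9 costimulation genes 5 rose, 7 adjusted over the list alone (mean 1.36, camera adjusted p = 0.000269; adjusted p = 0.274 with an estimated correlation), with Il18 (2.35), Cd86 (2.08), Cd80 (2.06) and Cd83 (1.72) among them. With the myeloid-like cells alone the costimulation mean turned to −0.069, the immunosuppressive mean was 0.14 and the MHC class II mean 0.045, and none was called (camera adjusted p = 0.967, 0.21 and 0.32). MHC class I genes, which most cells express, did not pass. For those 14 genes edgeR called 0, over all genes and adjusted over the list alone, and the mean of −0.02, the median of 0.01 and the test differed in sign without passing (adjusted p = 0.933 with an estimated correlation); Tapbp was at 0.51, Tap1 at 0.52, H2-Q7 at −0.72 and H2-K1 at −0.39 (edgeR adjusted p = 0.132, 0.148, 0.239 and 0.3).

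Inflammatory genes were also higher over all cells. Of 20 chemokine genes 10 rose and 1 fell (Ccl5), 12 and 1 adjusted over the list alone (mean 1.79, camera adjusted p = 2.01e-08; adjusted p = 0.274 with an estimated correlation). The monocyte attractant Ccl2 went from 87.1 ± 40.03 to 528 ± 182 CPM (log2 fold change 2.60, edgeR adjusted p = 0.00435), and Ccl7 (2.55), Pf4 (2.39) and Cxcl16 (2.15) rose too. Of 12 inflammatory cytokines 3 rose and 1 fell, 8 and 1 adjusted over the list alone (mean 1.20, camera adjusted p = 0.00164; adjusted p = 0.278 with an estimated correlation). Il1b rose from 1214 ± 549 to 5118 ± 1565 CPM (2.08, edgeR adjusted p = 0.0101) and Osm by 1.45 (0.0348), while the macrophage growth factor Csf1 fell by 1.08 on the log2 scale (0.0308). Of 28 type I interferon response genes 9 rose, 15 adjusted over the list alone (mean 0.90, camera adjusted p = 5.53e-06; adjusted p = 0.379 with an estimated correlation), such as Oas2 (2.41), Slfn5 (1.97), Oasl2 (1.93) and Ifi204 (1.64). Of 21 interferon-γ response genes 5 rose, 6 adjusted over the list alone (mean 0.74, camera adjusted p = 0.00812; adjusted p = 0.472 with an estimated correlation), such as Cxcl10 (2.09) and Gbp5 (1.11); the call of this list was lost without LAP-high 1 (mean 0.66, camera adjusted p = 0.104). With the myeloid-like cells alone the chemokine mean turned to −0.0077 and the cytokine mean to −0.31, the interferon-γ mean was 0.21, and these calls were lost (camera adjusted p = 0.81, 0.122 and 0.163). The type I interferon mean was 0.22 there (camera adjusted p = 0.0106, or 0.824 with an estimated correlation).

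Genes of uptake, digestion and matrix turnover were mostly higher over all cells. Of 19 phagocytic and scavenger receptors 15 rose and 1 fell on both counts, 15 and 1 adjusted over the list alone (mean 1.78, camera adjusted p = 1.98e-09; adjusted p = 0.274 with an estimated correlation), such as Msr1 (2.68), Fcgr2b (2.45) and C3ar1 (2.44). Of 22 lysosome and lipid genes 14 rose, and 16 rose and 1 fell adjusted over the list alone (mean 1.16, camera adjusted p = 2.86e-10; adjusted p = 0.274 with an estimated correlation), such as Cd36 (2.46), Hexa (1.78) and Ctsz (1.69). Of 18 matrix and angiogenesis genes 12 rose and 2 fell, 13 and 4 adjusted over the list alone (mean 0.99, camera adjusted p = 0.000246; adjusted p = 0.278 with an estimated correlation); Mmp19 rose, while Timp1 (−2.79) and the growth factor Ereg (−5.19) fell. Of 12 genes listed as neutrophil granule proteins 8 rose on both counts, 8 adjusted over the list alone (mean 1.97, camera adjusted p = 1.8e-06; adjusted p = 0.274 with an estimated correlation). Those named were Lyz2 (2.91; 10663 ± 5177 against 1420 ± 585 CPM), Cybb (2.51), Ncf1 (1.43) and Ncf4 (1.19), the lysozyme and oxidase subunits that macrophages also make, while neutrophil markers did not pass. With the myeloid-like cells alone the lysosome and lipid mean turned to −0.082, the matrix mean was 0.20 and the granule mean 0.24, and these calls were lost (camera adjusted p = 0.399, 0.0557 and 0.17). The phagocytic mean was 0.19 there (camera adjusted p = 0.0453, or 0.413 with an estimated correlation).

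Metabolic and general lists were compared as well. Of 15 glycolysis genes 3 rose, 4 adjusted over the list alone (mean 0.48, camera adjusted p = 0.00964; adjusted p = 0.274 with an estimated correlation), with Slc16a3 at 1.58, Hk2 at 1.55 and Pkm at 0.79; Slc2a1 at 0.90 did not pass (edgeR adjusted p = 0.0517). Of 16 hypoxia genes 5 rose, 7 adjusted over the list alone (mean 0.56, camera adjusted p = 0.00429; adjusted p = 0.337 with an estimated correlation), among them Mxi1 (1.56), Vegfa (1.54), Ero1l (0.99) and P4ha1 (0.85). Of 21 immediate early and heat shock genes 7 rose, and 7 rose and 2 fell adjusted over the list alone (mean 0.53, camera adjusted p = 0.0146; adjusted p = 0.315 with an estimated correlation), such as Atf3 (2.31), Nr4a1 (1.63), Fos (1.56) and Zfp36 (1.55). In the myeloid-like cells alone the glycolysis, hypoxia and immediate early means turned to −0.20, −0.26 and −0.037 (camera adjusted p = 0.32, 0.372 and 0.82). Of 28 cell cycle genes 1 fell, Ccnb1 (−1.95, edgeR adjusted p = 0.0456), and 0 adjusted over the list alone by edgeR (mean −0.66, camera adjusted p = 0.0015; adjusted p = 0.547 with an estimated correlation); Ube2c was at −1.73, Cdc20 at −1.65 and Cenpf at −1.50 (0.103, 0.121 and 0.137). Of 79 ribosomal protein genes 1 fell on both counts, 1 adjusted over the list alone (mean −0.70, camera adjusted p = 2.26e-07; adjusted p = 0.484 with an estimated correlation). That gene was Rpl39l (−4.37, edgeR adjusted p = 0.00396), while Rpl13a (−0.78), Rpl30 (−0.98) and Rpl36a (−1.27) did not pass. The cell cycle and ribosomal means were −0.43 and −0.38 in the myeloid-like cells alone (camera adjusted p = 0.00249 and 0.000535; adjusted p = 0.395 and 0.895 with an estimated correlation). Of 12 mitochondrially encoded genes edgeR called 0, over all genes and adjusted over the list alone (mean −0.02, camera adjusted p = 0.82), with mt-Nd2 at −0.29, mt-Cytb at −0.27, mt-Nd1 at −0.25 and mt-Rnr2 at 0.28, the last turning to −0.02 with no mitochondrial limit.

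**Figure D3:**
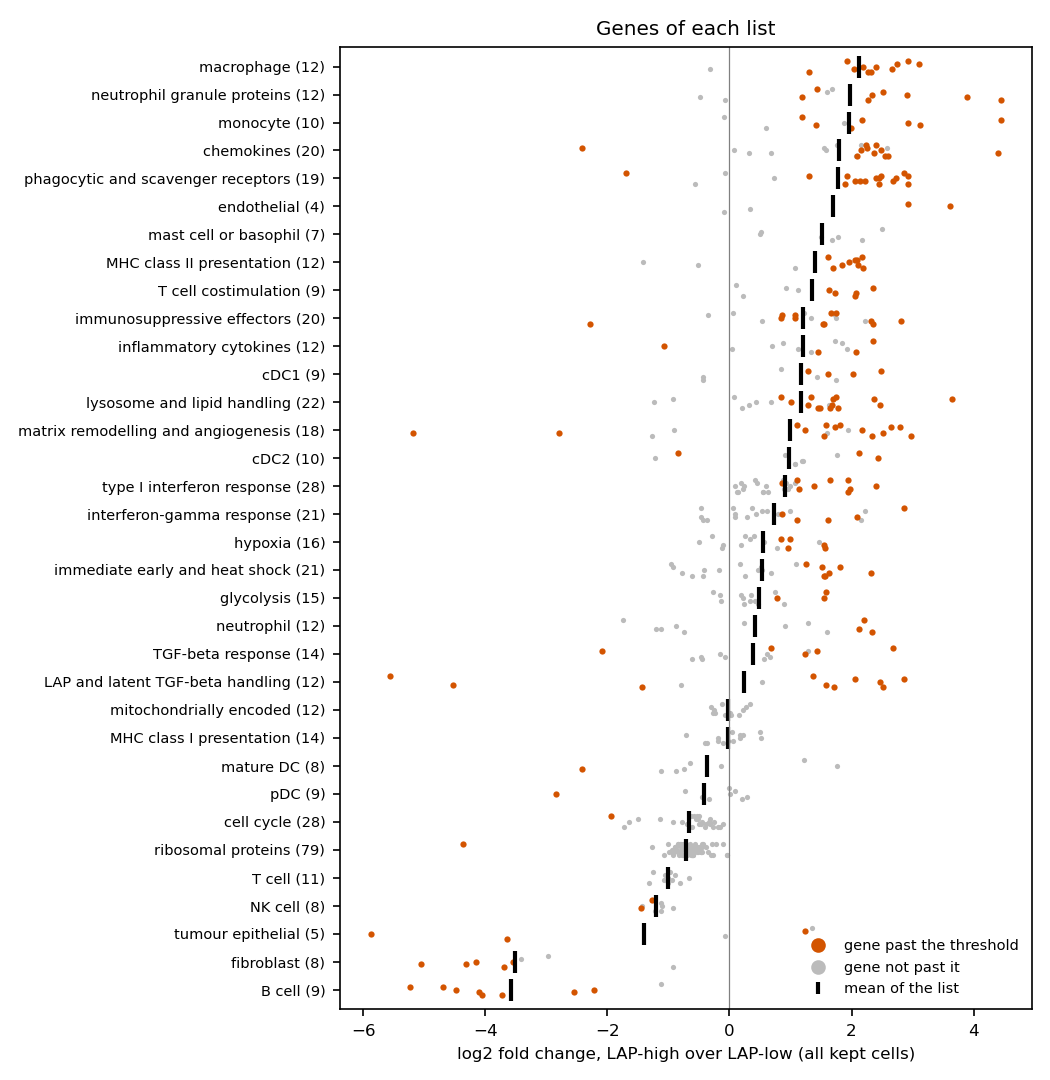
Log2 fold change of each tested gene, LAP-high over LAP-low in all kept cells, grouped by list with the number of genes in brackets; orange points passed the edgeR threshold, grey points did not, and the bar is the mean of the list. Macrophage markers average 2.13 and B cell markers −3.57.

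In all, camera called 24 of 34 lists, 18 higher and 6 lower, and fry called 22; with an estimated correlation camera called 0, with 5 at an unadjusted p under 0.05. Within batches A and B camera called 27 and 24, and in batch B the cDC2 (0.81) and interferon-γ calls (0.48) were lost (adjusted p = 0.19 and 0.448). List means in batches A and B were 2.52 and 1.86 for macrophage, 2.24 and 1.81 for monocyte, −0.99 and −1.45 for NK cell, and −0.69 and −1.46 for T cell markers. They were 2.02 and 0.85 for MHC class II, 1.27 and 0.57 for type I interferon, and 1.37 and 1.12 for immunosuppressive genes.

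Expression within monocyte/macrophage-like cells was compared to part a change within a cell type from a change of cell types. Only the light chain Igkc passed, with a log2 fold change of −5.33 (SE 0.496, edgeR adjusted p = 0.000294), from 31.7 ± 15.4 CPM in LAP-low to 0.850 ± 0.548 CPM in LAP-high libraries; it is a B cell gene, and was named after its value was seen. Gimap9 (−2.49) and the NK cell receptor Ncr1 (−2.07) had the next lowest p and did not pass (edgeR adjusted p = 0.37). Of 8855 genes tested 1 was called, 647 had an unadjusted p under 0.05, and DESeq2 called 12; 392 genes did not overlap between the groups, 4.43% where chance gives 2.86%. Batch A gave 0 and batch B 20 calls, and without LAP-high 1 or LAP-low 2 there were 4 and 2. With the replicate number as a block edgeR called 43 genes. After subtraction of free RNA edgeR called 0, with 258 at an unadjusted p under 0.05.

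Lists within these cells moved modestly, and 10 of 30 were called. Monocyte markers (mean 0.43, camera adjusted p = 0.00369) and neutrophil granule genes (0.50, 0.0125) were higher in LAP-high libraries, each with adjusted p = 0.418 with an estimated correlation. Type I interferon genes were higher over both batches (0.25, camera adjusted p = 0.00369; adjusted p = 0.883 with an estimated correlation), with means of 0.79 in batch A and −0.06 in batch B, and of 0.00437 without LAP-high 2 and 0.08 without LAP-low 3, where the call was lost. Glycolysis genes were lower, 15 of 15 negative (mean −0.39, camera adjusted p = 4.77e-05, or 0.418 with an estimated correlation). So were hypoxia genes, 14 of 14 (−0.49, 6.31e-05, or 0.581). Both lists were higher over all cells. Their per-library means in this class overlapped (exact permutation adjusted p = 0.49 and 0.623). No list within any class passed that test. Cell cycle genes (−0.46, camera adjusted p = 5.15e-05, or 0.42 with an estimated correlation) and ribosomal protein genes (−0.38, 4.2e-06, or 0.883) were lower too. The ribosomal mean was 0.04 without LAP-low 1. The call of the granule genes was lost without LAP-low 3 (mean 0.44). Markers of other cells fell beside them, with means of −1.80 for NK cell (camera adjusted p = 6.72e-12), −1.63 for mature DC (1.12e-05) and −0.86 for T cell markers (4.77e-05). With an estimated correlation their adjusted p = 0.199, 0.199 and 0.581. Over all genes edgeR called 0 genes of any of these lists, with 647 genes in all at an unadjusted p under 0.05; adjusted over the list alone 5 of 6 NK cell and 3 of 3 mature DC markers passed. In batches A and B the means were −0.34 and −2.26 for T cell markers, −0.26 and −0.93 for cell cycle and −0.25 and −0.48 for glycolysis genes, and these 3 calls were lost in batch A (camera adjusted p = 0.222, 0.0539 and 0.244). They were −0.41 and −0.52 for hypoxia genes and −1.05 and −3.01 for NK cell markers, called by camera in both. Lists for macrophage markers, MHC class II, immunosuppressive effectors, chemokines and latent TGF-β did not pass, with means between −0.15 and 0.15. Fry called 0 lists, with 4 at an unadjusted p under 0.05. After subtraction of free RNA the cell cycle call was lost (mean −0.44, camera adjusted p = 0.0747), and the NK cell, T cell and mature DC lists had too few genes left to test.

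In NK cell-like cells of LAP-high libraries the cell cycle list rose, with 20 of 23 genes positive (mean 0.68, camera adjusted p = 4.36e-19, or 0.0335 with an estimated correlation and no call with the block added, fry 0.0308), by 0.77 in batch A and 0.71 in batch B. Over all genes 1 of them passed and 12 adjusted over the list alone. That gene was Mcm4, a subunit of the helicase that opens DNA for replication, at 307 ± 44.4 against 154 ± 15.6 CPM (log2 fold change 0.99, SE 0.168, edgeR adjusted p = 0.047). The per-library mean of the list in log2 CPM was 5.99 ± 0.285 and 5.39 ± 0.276 (exact permutation p = 0.0571, adjusted p = 0.257, n = 4 each). The chemokine Ccl3 fell from 100.5 ± 19.05 to 39.6 ± 4.88 CPM (log2 fold change −1.33, SE 0.224, edgeR adjusted p = 0.047). Mcm4 lies on chromosome 16 from 15623897 to 15637400 and Ccl3 on chromosome 11 from 83647844 to 83649355, both on the minus strand, with no overlap.

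Interferon genes were lower in the same cells. Of 25 type I interferon response genes 23 had negative values (mean −0.61, camera adjusted p = 1.11e-10; adjusted p = 0.22 with an estimated correlation), −0.67 in batch A and −0.57 in batch B. Interferon-γ genes (−0.37, camera adjusted p = 9.22e-05, or 0.103 with an estimated correlation) and T cell markers (−0.50, 0.0007, or 0.103) were lower too. Chemokines were as well (−0.39, 0.00793, or 0.448). So were cDC2 (−0.88, 0.0273), mature DC (−0.73, 0.0425), immediate early (−0.32, 0.0425), ribosomal (−0.23, 0.0348) and mitochondrially encoded genes (−0.19, 0.0374), by camera. With an estimated correlation their adjusted p = 0.285, 0.279, 0.456, 0.756 and 0.534. These 5 calls each depended on single libraries. The cDC2 call was lost without LAP-low 1, LAP-low 2 or LAP-high 3 (means −0.72, −0.67 and −0.59), and the mature DC call without LAP-high 1, LAP-low 1, LAP-high 4 or LAP-low 4 (−0.48, −0.53, −0.76 and −0.70). The immediate early call was lost without LAP-high 1 or 3 (−0.24 and −0.22) or LAP-low 1, 3 or 4 (−0.32, −0.25 and −0.29), the ribosomal call without LAP-high 3 or 4 (−0.13 and −0.14), and the mitochondrial call without LAP-high 2, LAP-low 2 or LAP-low 4 (−0.03, −0.18 and −0.17). Phagocytic receptors (1.34, camera adjusted p = 1.27e-05), latent TGF-β genes (0.58, 0.00793) and MHC class II genes (0.55, 0.0348) were higher. With an estimated correlation their adjusted p = 0.103, 0.22 and 0.286. The latent TGF-β call was lost without LAP-low 1 (mean 0.40), and the MHC class II call without LAP-low 1 or 4 (0.56 and 0.41) or LAP-high 2, 3 or 4 (0.54, 0.31 and 0.51). Without LAP-low 1 the ribosomal mean turned to 0.24, and without LAP-low 3 the chemokine mean turned to 0.23. After subtraction of free RNA the phagocytic mean went to 0.35 (camera adjusted p = 0.395), the latent TGF-β mean to 0.31 (0.0544), the MHC class II mean to 0.43 (0.404) and the T cell mean to −0.26 (0.0815), and these calls were lost. So were the cDC2 (−0.90, 0.0619), immediate early (−0.34, 0.0544), ribosomal (−0.21, 0.0619) and mitochondrial calls (−0.14, 0.103, by camera), while the cell cycle, chemokine and both interferon lists were still called. Within batch A the MHC class II (0.17, camera adjusted p = 0.373) and immediate early calls (−0.25, 0.336) were lost, and within batch B the latent TGF-β (0.44, 0.0764) and mitochondrial calls (−0.093, 0.33). The mature DC mean was −1.80 in batch A and −0.22 in batch B, and in batch B the T cell mean was −0.29 and the ribosomal mean −0.12. NK cell markers did not pass (mean −0.22, camera adjusted p = 0.0912). Adjusted over the list alone, 4 T cell markers and 3 chemokines were lower and 1 phagocytic receptor was higher.

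In these cells 4 of 9223 genes were called, 628 had an unadjusted p under 0.05 and DESeq2 called 18. With the replicate number as a block edgeR called 171, these 4 among them. Besides Mcm4 and Ccl3 they were Scarb1, a lipoprotein receptor (log2 fold change 3.43, SE 0.571; 15.2 ± 5.25 against 1.18 ± 0.730 CPM), and Cma1, a mast cell protease (−2.63, SE 0.427; 3.11 ± 2.36 against 25.01 ± 4.43 CPM), both with edgeR adjusted p = 0.047 and named after their values were seen. Batch A gave 0 and batch B 24 calls, and removing any 1 library except LAP-low 1 (20 calls) left 0. LAP-high 2 had 25 cells of this class and 144049 counts. NK clusters 0, 4, 17 and 20 held 56.5%, 31.2%, 9% and 3.33% of these cells in LAP-high and 49.9%, 36.4%, 8.87% and 4.84% in LAP-low libraries.

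**Figure D4:**
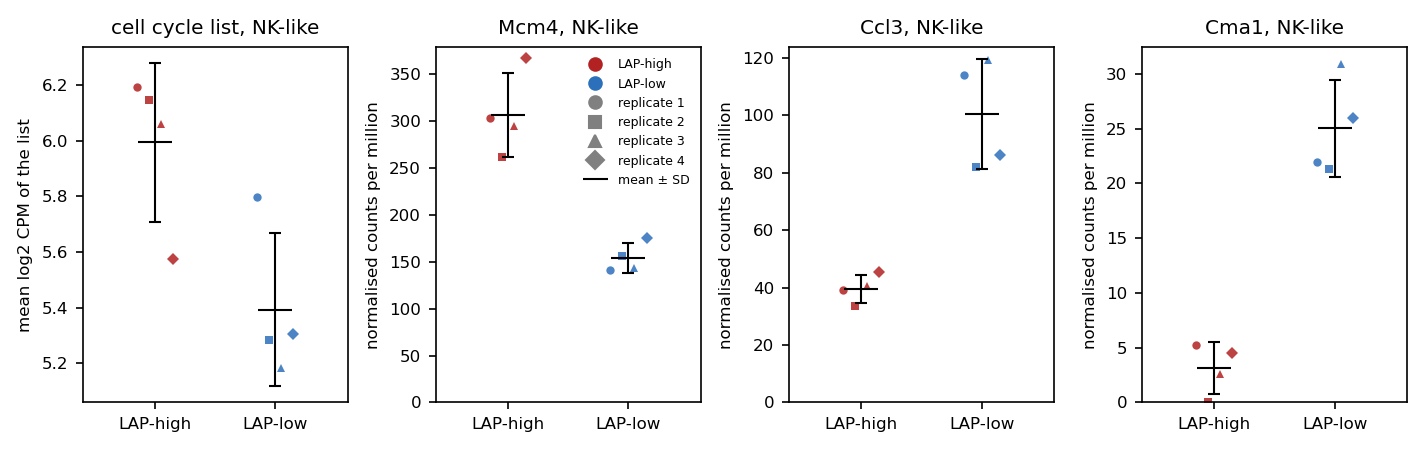
NK cell-like cells, with the mean log2 CPM of 23 cell cycle genes and the normalised CPM of Mcm4, Ccl3 and Cma1, 1 point per library with marker shapes for the replicate number and mean ± SD (n = 4). Mcm4 averages 307 CPM in LAP-high and 154 CPM in LAP-low libraries, without overlap.

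In T cell-like cells granzyme A, Gzma, a protease of cytotoxic granules, was lower in LAP-high libraries, at 184 ± 84.8 against 1074 ± 297 CPM (log2 fold change −2.58, SE 0.337, edgeR adjusted p = 0.0181). It lies on chromosome 13 from 113093825 to 113100981 on the minus strand with no overlap. NK cell markers, Gzma among them, fell as a list (mean −0.87, camera adjusted p = 2.21e-09, adjusted p = 0.0338 with an estimated correlation, fry 0.116), with 1 of 7 called over all genes and 3 adjusted over the list alone, by −0.89 in batch A and −0.9995 in batch B. Cell cycle genes rose here too (mean 0.56, camera adjusted p = 1.23e-10; adjusted p = 0.181 with an estimated correlation), with edgeR calling 0 of 21 over all genes and 7 adjusted over the list alone, by 0.52 and 0.55 in batches A and B. Mature DC (−0.76, camera adjusted p = 0.0142), ribosomal (−0.28, 7.96e-05) and mitochondrially encoded genes (−0.28, 0.017) were lower. With an estimated correlation their adjusted p = 0.767, 0.906 and 0.906. The mature DC call was lost without LAP-high 1, LAP-low 3 or LAP-high 4 (means −0.63, −0.59 and −0.66), the ribosomal call without LAP-high 3 or 4 (−0.16 and −0.15), and the mitochondrial call without LAP-high 2 or 3 (−0.17 and −0.22) or LAP-low 2 or 4 (−0.25 and −0.23). Without LAP-low 1 the ribosomal mean turned to 0.12, and in batch B it was −0.48. The mature DC and mitochondrial calls were lost in batch A (−0.81 and −0.21, camera adjusted p = 0.0757 and 0.212) and in batch B (−0.61 and −0.41, 0.0539 and 0.0551). After subtraction of free RNA the mitochondrial call was lost (mean −0.20, camera adjusted p = 0.18), and NK cell markers stood at −0.85 (1.65e-07). With the replicate number as a block, which paired the libraries in these cells, edgeR called 6 genes, Gzma among them (−2.66, edgeR adjusted p = 0.000151). The cDC2 list was then called too (mean −0.98, camera adjusted p = 0.0152; adjusted p = 0.521 with an estimated correlation). The NK cell marker call was lost with the block and an estimated correlation (mean −0.99, camera adjusted p = 0.174). T cell markers did not pass (mean −0.08). Of 8132 genes tested 1 was called, 263 had an unadjusted p under 0.05 and DESeq2 called 3; edgeR gave 1 other call in batch A and 0 in batch B, where Gzma stood at −2.75 and −2.41. Without LAP-high 1, LAP-high 3, LAP-low 3 or LAP-high 4 Gzma stood at −2.37, −2.73, −2.57 and −2.46 and edgeR called 0 genes. T clusters 2, 7 and 12 held 42.2%, 41.3% and 16.5% of these cells in LAP-high and 54.4%, 29.4% and 16.1% in LAP-low libraries.

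In pDC-like cells Serpinb9, an inhibitor of granzyme B, was lower in LAP-high libraries, at 59.2 ± 14.1 against 284 ± 47.1 CPM (log2 fold change −2.34, SE 0.348, edgeR adjusted p = 0.00285). The long noncoding gene AW112010 was lower as well, at 45.8 ± 15.7 against 296 ± 151 CPM (−2.66, SE 0.432, edgeR adjusted p = 0.00488). Serpinb9 lies on chromosome 13 from 33003250 to 33017957 on the plus strand and AW112010 on chromosome 19 from 11047612 to 11055808 on the minus strand. Of 2297 genes tested these 2 were called, 105 had an unadjusted p under 0.05 and DESeq2 called 3; edgeR gave 2 calls of other genes in batch A and 26 calls in batch B, and without LAP-high 1, 2, 3 or 4 there were 5, 7, 5 and 7 and without LAP-low 1 or 2 there were 5 and 6. Ribosomal protein genes were lower, 38 of 38 with a negative value (mean −0.50, camera adjusted p = 8.6e-11, or 0.67 with an estimated correlation). So were glycolysis genes (−0.45, 0.0197, or 0.642) and immunosuppressive effectors (mean −1.29, median −0.35, 0.00451, or 0.241). Camera called these 3 of 17 lists. In batches A and B the ribosomal means were −0.30 and −0.82; the glycolysis call was lost in batch A (−0.48, camera adjusted p = 0.0525) and the immunosuppressive call in batch B (−0.58, 0.09), with too few genes to test in batch A. Free RNA was estimated at 32.8% to 78.5% of the counts of this class in LAP-low and 2.47% to 42.9% in LAP-high libraries. After its subtraction the ribosomal mean was −0.15 (camera adjusted p = 0.0216), the glycolysis mean was −0.079 and its call was lost (0.345), and the immunosuppressive list had too few genes left to test. The immunosuppressive mean was −0.64 without LAP-high 1 and −1.14 without LAP-high 2, where its call was lost, and the glycolysis call was lost without any 1 of LAP-low 1, 2 and 3 and LAP-high 2 and 3 (means from −0.49 to −0.30).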

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

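No test in this part was chosen after its result was seen. In groups of 4 libraries, a library was singled out when its gap to the nearest of the others took up nearly all of the range of the group (Dixon's test at 95%). Of 278 groups of values 22 had such a library, 7.91%, where chance sets off about 1 in 20 groups. None of the values below is explained here.

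LAP-high 1 stood apart for 10 of the values. It held 12.5% of its cells in cluster 10, the cluster led by Mki67 and Top2a, where the other LAP-high libraries held between 0.917% and 2.82%. Fibroblast/tumour-like cells were 1.24% of its cells and between 0% and 0.183% of the others. Over all cells its levels in CPM, with the range of the other LAP-high libraries, were 9.56 for Cavin2 (0.757 to 1.92), 31.5 for Mt2 (5.31 to 9.47), 162 for H2-Q7 (49.2 to 53.4), 27.7 for Ube2c (2.88 to 5.30) and 5.48 for Rpl39l (0.757 to 1.55). It was below the others for C3ar1, at 185 CPM (436 to 460.5), and P4ha1, at 119 CPM (189 to 195). In its monocyte/macrophage-like cells Gimap9 stood at 6.95 CPM (1.91 to 2.62).

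LAP-low 2 stood apart for 7 genes over all cells. Its levels in CPM, with the range of the other LAP-low libraries, were 188 for Cavin1 (63.7 to 68.9), 546 for Col1a2 (143 to 186), 450.0 for Baiap2l1 (121 to 167) and 184 for Slc30a4 (63.1 to 82.2). It was below the others for Lyz2, at 549 CPM (1617 to 1762), Ero1l, at 73.2 CPM (116 to 122), and Ptpro, at 4.22 CPM (14.7 to 15.2).

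The other 5 values belong to further LAP-low libraries. LAP-low 3 had 5.04% pDC-like cells (1.53% to 1.95% in the others), 1.92 CPM of Lrrc32 over all cells (0.513 to 0.703) and 104 CPM of Ncr1 in monocyte/macrophage-like cells (56.8 to 62.7). In LAP-low 4 Ccl2 stood at 147 CPM over all cells (60.3 to 72.7). In LAP-low 1 Gimap9 stood at 29.7 CPM in monocyte/macrophage-like cells (13.4 to 15.95).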

How the results depend on the processing

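The batch term, fits within a batch, subtraction of free RNA, the myeloid-like cells alone, and the block with an estimated correlation were tests chosen only after the results were seen; the other alternatives were set before the data were examined. Where a value moved, the cause was not tested, unless the alternative itself leaves fewer libraries or other cells. Named genes over all their alternatives kept direction and side of the threshold in 2235 cases, passed newly in 63, no longer passed in 301 and turned in 17. For single lists, by the direction that camera gives, these counts were 2695, 83, 251 and 11, for class shares 93, 1, 64 and 9, and for the 3 LAP genes 53 were kept and 14 no longer passed. Lists were not computed with DESeq2, without the filter on low counts or from per-cell CPM. Simulated 2-fold changes were recovered in 16% of cases over all cells and 24.5% to 53.5% within the classes, so many changes of that size would be missed at this depth and spread.

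Over all cells the 2062 calls of edgeR became 1999 with other size factors, 2619 with a batch term, 2799 with DESeq2, 3015 without the filter on low counts, 2094 and 2008 with looser and stricter limits, 2728 without the mitochondrial limit, 1938 without doublets, 2653 with all barcodes, 1877 after thinning, and 2531 with per-cell CPM in limma. They were 0 within batch A, where only 2 libraries per group remain (1678 at an unadjusted p under 0.05), 3169 within batch B, and 102 with the myeloid-like cells alone. Leaving out 1 library gave 1066 to 3954. The number of lists called went from 24 to 0 with an estimated correlation (5 at an unadjusted p under 0.05) and to 13 with the myeloid-like cells alone.

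In the myeloid-like cells alone these log2 fold changes turned: Mmp14 −0.043, Id1 −0.16, Il1b −0.059, Osm −0.32, Slc16a3 −0.22, Slc2a1 −0.40, P4ha1 −0.012, Ero1l −0.064, Timp1 0.11 and Ncf1 −0.30. So did the means of 11 lists: neutrophil (−1.66), cDC1 (−0.022), cDC2 (−0.65), inflammatory cytokine (−0.31), glycolysis (−0.20), hypoxia (−0.26) and, as above, chemokine, lysosome and lipid, costimulation, immediate early and TGF-β response. Tgfb1 at 0.80 and Nrros at 0.46 no longer passed there. Within batch A Tgfb1 at 1.96, Lrrc32 at 2.15 and Nrros at 2.497 no longer passed. With 1 library left out Tgfb1 ran from 1.34 to 1.98 and Lrrc32 from 2.13 to 3.02. The mitochondrial gene mt-Rnr2 turned to −0.017 without the mitochondrial limit, −0.010 with all barcodes and −0.048 with per-cell CPM.

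In monocyte/macrophage-like cells the 1 call became 20 in batch B, 105 without the filter on low counts and 12 with DESeq2. edgeR gave 0 in batch A (391 at an unadjusted p under 0.05), with looser (584) or stricter limits (566), without the mitochondrial limit (551), at cluster resolutions 0.5 (638) and 2.0 (573) and after subtraction of free RNA (258). Without 1 library it gave 1 to 4. The 10 lists called became 0 with an estimated correlation (3 at an unadjusted p under 0.05), 0 with fry (4) and 6 after subtraction of free RNA. The cDC2 mean ran from −0.84 to −0.16 without 1 library.

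In NK cell-like cells the 4 calls became 15 with a batch term, 24 in batch B, 44 without the filter on low counts, 18 with DESeq2, 1 without the mitochondrial limit and 1 at resolution 0.5. edgeR gave 0 with other size factors (623 at an unadjusted p under 0.05), in batch A (194), with looser (615) or stricter limits (340), without doublets (616), at resolution 2.0 (332) and after subtraction of free RNA (616), and 0 to 20 without 1 library. The 13 lists became 1 with an estimated correlation, 2 with fry, 8 at resolution 2.0 and 4 after subtraction of free RNA. Without 1 library 8 to 14 were called, and the ribosomal mean ran from −0.51 to 0.24.

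In T cell-like cells the 1 call became 12 without the filter on low counts and 3 with DESeq2. edgeR gave 0 in batch B (218 at an unadjusted p under 0.05), with stricter limits (234), without the mitochondrial limit (261), without doublets (259) and after subtraction of free RNA (235), and 0 to 1 without 1 library. The 5 lists became 1 with an estimated correlation, 0 with fry (2 at an unadjusted p under 0.05), 3 in batch B and 8 without the mitochondrial limit, where the MHC class II mean turned to 0.63. Without 1 library 4 to 9 were called, the ribosomal mean ran from −0.50 to 0.12 and Tgfb1 from −0.033 to 0.43, with −0.14 in batch B.

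In pDC-like cells the 2 calls became 26 in batch B, 39 without the filter on low counts, and 1 each with looser limits, stricter limits and no mitochondrial limit. edgeR gave 0 without doublets (104 at an unadjusted p under 0.05) and after subtraction of free RNA (87), where DESeq2 on the unaltered counts called 3, and 2 to 7 without 1 library. The 3 lists became 0 with an estimated correlation (1 at an unadjusted p under 0.05), 0 with fry (1), 5 in batch B and 5 without the mitochondrial limit, and 1 to 5 without 1 library. The matrix and angiogenesis mean, −0.52 over all libraries, was −1.53 in batch A and 0.31 in batch B.

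Of the class shares, 7 passed as reported and 5 to 7 at other resolutions, limits or on log odds. Without doublets none of them passed by the exact permutation test, with nearly the same differences in percentage points. These were 49.9 for monocyte/macrophage-like, −19.4 for NK cell-like, −24.3 for T cell-like, −11.0 for fibroblast/tumour-like and 1.95 for conventional DC-like cells and 4.71 for cluster 11 (Benjamini-Hochberg adjusted p = 0.0571), and −3.76 for cluster 16 (0.171). Fewer classes then reach the smallest p. The pDC-like difference turned to 0.0292 with stricter limits, 0.0808 without doublets and 0.077 on log odds. With 1 library left out, 6 of the 7 classes no longer passed in 7 of 8 cases and cluster 16 in 8 of 8, and the differences ran from 45.1 to 58.0 for monocyte/macrophage-like, −23.1 to −16.8 for NK cell-like, −26.1 to −22.1 for T cell-like, −12.3 to −8.32 for fibroblast/tumour-like, 1.63 to 2.06 for conventional DC-like and −0.409 to 0.759 for pDC-like cells. They ran from −1.69 to 2.16 for cluster 10, 4.05 to 5.02 for cluster 11, 0.915 to 1.92 for cluster 13 and −4.79 to −1.53 for cluster 16.

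Outside T cell-like sums the replicate numbers did not meet the condition for pairing, a correlation over 0.1 in every pair. All but pDC-like sums had 3 of 4 over it, so counts and tests of chance that ignore pairs stay unsettled. Deviations of libraries with the same number correlated by −0.130 to 0.470 over all cells, over 0.1 in 3 of 4 pairs, and 6 of 8 libraries correlated best with their own number. The range was 0.0890 to 0.397 in monocyte/macrophage-like (7 of 8 best with their own number), 0.0573 to 0.427 in NK cell-like (5 of 8) and −0.174 to 0.147 in pDC-like cells (2 of 8). With the number as a block edgeR called 3011 genes over all cells, 43 in monocyte/macrophage-like, 171 in NK cell-like, 6 in T cell-like and 2 in pDC-like cells. With the block and an estimated correlation camera called 0 lists in all 5 comparisons (2, 4, 7, 2 and 1 at an unadjusted p under 0.05). Sign flips of the paired differences of shares, whose smallest p is above the threshold with 4 pairs, gave adjusted p = 0.188 in an exact test for each of the 7 classes that had passed (−19.6, −24.2, 4.52, −3.70, 1.84, −10.9 and 50.4 percentage points).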

Other observations

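The tests of the myeloid-like cells alone, of the monocyte/macrophage sub-clusters, of library depth over all cells, of free RNA and of other splits of the libraries were chosen only after the results were seen. Those of the cell mix, of the depth of NK sums and of cycling NK-like cells were set before. In the myeloid-like cells alone (monocyte/macrophage-like, neutrophil-like, conventional DC-like and pDC-like cells and cluster 11), 8 genes were higher in LAP-high libraries, named after their values were seen. Acvr1, a type I receptor for activins and bone morphogenetic proteins, stood at 17.8 ± 2.24 against 6.09 ± 1.40 CPM (log2 fold change 1.52, SE 0.293, edgeR adjusted p = 0.0306; 1.82 and 1.40 in batches A and B; n = 4 each). The sulfatase Sulf2 stood at 123 ± 15.8 against 54.1 ± 10.1 CPM (1.16, SE 0.184, edgeR adjusted p = 0.0138; 1.30 and 1.13), and selenoprotein P, Selenop, at 391 ± 80.6 against 186 ± 50.1 CPM (1.07, SE 0.220, edgeR adjusted p = 0.0392; 1.03 and 1.16). The others were Colec12 (0.98), Dna2 (1.19), Gm44751 (0.80), Nuak2 (1.02) and Nxpe5 (1.52), with edgeR adjusted p from 0.0255 to 0.0484. Within monocyte/macrophage-like cells alone all 8 had positive values and none passed, with 0.90 for Sulf2 (edgeR adjusted p = 0.37), 0.84 for Selenop and 1.41 for Acvr1 (0.497 both). The 94 lower genes included 7 of 12 neutrophil and 6 of 8 pDC markers. S100a9 fell from 1702 ± 652 to 199.9 ± 130 CPM (−3.09, edgeR adjusted p = 0.00814), and Siglech, a pDC receptor, from 654 ± 320.2 to 153 ± 62.2 CPM (−2.08, 0.0213). S100a9 stood at 0.37 within monocyte/macrophage-like cells (edgeR adjusted p = 0.91). In these libraries 101 neutrophil-like and 152 pDC-like cells stood beside 3592 monocyte/macrophage-like cells in LAP-high, and 163 and 155 beside 732 in LAP-low. Neutrophil (−1.66) and pDC markers (−1.97) were lower and monocyte (0.49) and macrophage markers (0.37) higher by camera, with the p-values given above. NK cell (−1.78, camera adjusted p = 3.15e-09), T cell (−1.08, 2.62e-06) and B cell markers (−1.44, 3.83e-06) were lower as well. With an estimated correlation their adjusted p = 0.209, 0.363 and 0.117. Camera called 6 further lists, type I interferon, phagocytic receptors, mature DC, cDC2, ribosomal and cell cycle genes, but none with an estimated correlation. The interferon mean was 0.86 in batch A and −0.16 in batch B, and the mature DC mean −2.09 and −0.0070. Of 35 splits of the 8 libraries only the real one reached 102 calls (highest other 0 by edgeR), the lowest share possible. Chance is less likely.

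Shares of 6 clusters within the monocyte/macrophage-like class were compared, and none passed after adjustment. Cluster 5, led by Hp, Cd177 and Chil3, genes of young monocytes and granulocytes, was 17.9% ± 9.30 of the class in LAP-high and 5.55% ± 2.35 in LAP-low libraries (exact permutation p = 0.0286, Benjamini-Hochberg adjusted p = 0.0857 over 6 clusters; higher in 4 of 4 libraries of the same number; 10.5 and 14.2 percentage points in batches A and B). Cluster 19, led by the complement genes C1qa, C1qb and C1qc and by Stab1, genes of resident macrophages, was 3.81% ± 0.501 and 6.96% ± 0.993 (exact p = 0.0286, adjusted p = 0.0857; −3.39 and −2.91). Cluster 8, led by the interferon-induced genes Rsad2 and Cxcl10, was 15.5% ± 4.62 and 9.06% ± 3.56 (exact p = 0.0857, adjusted p = 0.171; 7.56 and 5.26). In cluster 13, led by Foxp3, Lrrc32 stood at 139 ± 79.2 CPM in LAP-high and 21.4 ± 19.99 CPM in LAP-low libraries (exact permutation p = 0.0571, Benjamini-Hochberg adjusted p = 0.514 over 15 tests, n = 4 each). The 82 and 7 counts behind these levels are few.

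The 2062 genes called over all cells stood beside large class differences. If each cluster had the same profile in both groups, cluster shares alone would give a median of 0.919 of the log2 fold change of called genes (quartiles 0.783 and 1.03). The sign matched for 2054 of 2062. A different mix of clusters, several within 1 class, may account for most of the calls. On the log2 ratio of group mean CPM without TMM scaling and with 0.5 added, a lower scale than the fitted fold changes, the mix predicts 0.04 of 1.70 for Lrrc32, 0.92 of 1.31 for Tgfb1 and 1.48 of 1.67 for Nrros, which leaves the Lrrc32 difference open. A difference in library depth is argued against, since 1753 of the genes were also called by edgeR after thinning every library to the same total. Chance is less likely, as only the real one of 35 splits gave as many calls (highest other 1269). Neither class mix alone nor why the fractions differ in cell classes, by LAP on each class or by the separation itself, was tested.

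RNA from other cells is a candidate explanation for the calls of Igkc in monocyte/macrophage-like and of Serpinb9 and AW112010 in pDC-like cells, since free RNA predicts a median of 0.944 of their differences (0.804, 0.944 and 1.14), and after its subtraction edgeR called 0 genes in either (258 and 87 at an unadjusted p under 0.05). For Gzma in T cell-like cells free RNA predicts 0.306 of the difference, and its subtraction moved the log2 fold change from −2.58 (SE 0.337) to −2.45 (SE 0.379), where the larger error ended the call (edgeR adjusted p = 0.132). After subtraction 0.949 of the log2 fold change was left and NK cell markers stood at −0.85 (camera adjusted p = 1.65e-07, −0.87 before). This argues against free RNA as the whole cause. A part, and doublets or NK cells placed in this class, which subtraction does not remove, stay open. Without doublets edgeR called 0 genes. Chance cannot be excluded for the counts in monocyte/macrophage-like, pDC-like and T cell-like cells: 3, 2 and 5 of 35 splits gave as many calls, with 1, 2 and 1 real and 3, 3 and 115 in the highest other split. A split of monocyte/macrophage-like sums with 3 calls follows the batches (1 call with a batch term), and the 115 calls of replicates 1 and 3 against 2 and 4 in T cell-like sums, a split that keeps libraries of the same number together, point to a structure of the samples, while among the 8 splits that part all 4 pairs, too few for a share under 0.05, the real one gave 1 and the highest other 0 by edgeR (263 genes at an unadjusted p under 0.05 in the real one).

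Higher cell cycle RNA in NK cell-like cells of LAP-high libraries, 0.602 in mean log2 CPM (exact permutation p = 0.0571, adjusted p = 0.257, n = 4), was weighed against 3 technical explanations. Free RNA, the depth of the sums and cycling NK cells assigned to the cycling cluster are each argued against as the whole cause. Of the difference, 1.24 was left after subtraction of free RNA, 1.01 after thinning and 0.872 with the NK-like cells of cluster 10 added (0.525, exact p = 0.0857). Cycling cells taken by this rule were 17.9% ± 4.41 of NK-like cells in LAP-high and 6.96% ± 3.68 in LAP-low libraries (exact permutation p = 0.0571, n = 4 each). Their ranges overlapped (11.3% in LAP-high 3, 11.6% in LAP-low 1), and LAP-high 2 rested on 6 of them beside 25 cells of the class. That the LAP-high fraction may hold more NK cells in cycle stays a hypothesis that this test did not pass. For the 4 genes called in these cells free RNA predicts at most 0.0365 of the difference, which argues against it, although after its subtraction Mcm4 (1.01, SE 0.168) and Ccl3 (−1.42, SE 0.229) kept their folds but not their calls (edgeR adjusted p = 0.0701 for both). Chance cannot be excluded for that count, since 2 of 35 splits gave as many calls, and the highest other, 14, parts replicates 1 and 2 from 3 and 4 and so follows the batches (15 calls with a batch term, 0 and 24 within batches A and B, by edgeR; 194 at an unadjusted p under 0.05 in A and 18 calls by DESeq2 over all libraries).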
